A study of Mus musculus with 24 samples.

How the data were processed

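Gene expression was measured by RNA sequencing in 24 libraries from mouse lung organoid cultures, 12 from the epithelial fraction and 12 from the fibroblast fraction. Per the labels' protocols, 300 ng of total RNA went into each library, and sequencing on a NextSeq 500 gave a mate carrying a stochastic barcode and the start of the fragment and a mate carrying only the other barcode. Per the submitters' processing notes, the authors used bcl2fastq, FastQC, cutadapt 1.12 and HISAT2 2.1.0 with the mouse build mm10. The counting program, the annotation release, the strand setting and the use of the barcodes are not given in the sources used here. The deposited values were raw counts, whole numbers with a different total in each library, and the authors had not normalized or pooled them.

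The deposited counts were per Ensembl transcript. Isoforms of a gene share exons, and how reads were shared among them is not given in the sources used here and was not tested. The counts of the 2 highest transcripts of a gene had a Pearson r of 0.891 across 11637 genes (log2 mean count). So that no read would count more than 1 time in a gene, each gene was represented by its transcript with the highest mean count over the 12 epithelial libraries, a choice made after the table had been seen. The 71081 transcripts covered 14557 gene symbols, of which 2920 had a single listed transcript. Of the transcript identifiers, 70518 were found in GENCODE M21 (build GRCm38, the same assembly as mm10), which gave coordinates, transcript lengths and GC content. The lowest total of a transcript over the epithelial libraries was 60, so low transcripts had been removed before deposit.

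The fibroblast columns held 107814 entries, 36733 of them below the last transcript identifier, and 9604 were 0 in all 12 libraries. Entry by entry they had no relation to the epithelial columns (Spearman rho = 0.0467). The entry pairs that belong to the same gene in the epithelial columns were unrelated in the fibroblast columns (Pearson r = 0.007). The identifiers were therefore used for the epithelial columns only. Fibroblast entries were tested without names, and no gene, gene list or fibroblast covariate is given for that fraction. A planned comparison of both fractions in the controls and the planned tests of a dose effect that differs between the fractions could not be run for the same reason. No column of per-sample values was left unused.

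Groups came from the sample titles, which give the fraction, the fiber number and the mouse (1 to 4). The tests, comparisons, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. For each fraction the 12 libraries of all 3 dose groups entered a single fit of edgeR 4.0.16 (R 4.3.3), leaving 9 residual degrees of freedom. Entries were filtered with filterByExpr by group and normalized by TMM, dispersions were estimated robustly, and the quasi-likelihood F test (glmQLFit, glmQLFTest) was applied. Genes with a Benjamini-Hochberg adjusted p under 0.05 were counted as changed. Standard errors of log2 fold changes were derived from the F statistic. CPM values (counts per 1e6 counts) use the TMM-scaled total of the representative transcripts, which ran from 2799765 to 10583357.

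Of the 36 gene lists, 33 had at least 3 tested members and were tested with camera (limma 3.58.1, 2-sided, preset correlation 0.01, Benjamini-Hochberg over the lists of a comparison). Camera with an estimated correlation and fry were alternatives. The lists covered ciliated cells, club and secretory cells, goblet cells and mucins, basal cells, alveolar type 2 cells, alveolar type 1 cells, transitional alveolar cells, neuroendocrine and tuft cells, pan-epithelial genes, fibroblast identity, myofibroblast and matrix genes, fibroblast growth factors for epithelium, Hox genes, proliferation, cholesterol synthesis, fatty acid synthesis and lipid storage, aryl hydrocarbon receptor targets, NRF2 targets, the unfolded protein and integrated stress response, inflammation, the interferon response, MHC class II antigen presentation, p53 targets, hypoxia and glycolysis, oxidative phosphorylation, cytosolic ribosomal proteins, WNT targets, the NOTCH pathway, the TGF-beta and BMP response, YAP targets, immediate early and heat shock genes, immune cells, endothelial and mesothelial cells, Y-linked genes, Xist and metallothioneins. Y-linked genes, Xist and metallothioneins had under 3 tested members and are given as single genes. Hoxa5 is known as a gene the study itself picked, so its list is not independent evidence.

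For each comparison the rule named the 10 largest rises and the 10 largest falls among changed genes with a mean log2 CPM of at least 1, the same direction in all 4 same-mouse pairs and a symbol that is not a predicted gene or pseudogene. It added up to 4 members of each list by smallest p, or up to 2 as values where none passed, and the fixed genes Epcam, Sftpc, Scgb1a1, Foxj1, Muc5ac, Krt5, Hoxa5, Col1a1, Acta2, Fgf7, Fgf10, Mki67 and Cyp1b1. The rule gave 276 symbols, and the text names a part of them. Some are not reported here. The filter on predicted names was widened after a clone name had passed it.

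Alternatives were the mouse number as a block, DESeq2 1.42.0, RLE and upper quartile normalization, no filter on low counts, a mean count of at least 10, an absolute log2 fold change of at least 1, only the 2 groups compared, each library left out in turn, and the mean level of the fibroblast identity list as a covariate. Counts summed over transcripts, every transcript tested, removal of a trend with transcript length and GC content, and thinning of all libraries to the lowest total were added after seeing the data. The mouse numbers pair the libraries because the labels tie each number to a cell isolation from that animal. Deviations from the group means correlated between same-mouse libraries at r = -0.03 to 0.184 across genes in the epithelial fraction and r = -0.076 to 0.436 in the fibroblast fraction. The 36 pairs of replicates differed by more than sampling noise (chi-square per degree of freedom 1.44 to 17.51), so none of the libraries was a copy of another. The p-values measure spread between these cultures, from 4 mice and a single fibroblast line.

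The tests were tried on simulated counts with 100 genes changed by a log2 of 1 and 100 by a log2 of 2. In the epithelial comparison at 12000 fibers, 98% and 100% were recovered with 15 false calls, and at 30000 fibers 91% and 99% with 12 false calls, over 13659 and 13622 genes. In the fibroblast fraction 95% and 100% were recovered at 12000 fibers and 93% and 100% at 30000 fibers, over 54393 and 54439 entries. All other genes were simulated as unchanged, and no mouse effect was built in. The real comparisons with control called far more genes or entries, so these rates hold only for the simulated setting. The position of reads within genes was followed only indirectly, in 3869 genes, as the log2 ratio of the isoform nearest the 3′ end to the isoform nearest the 5′ end, against the control mean. Values of Itga6, Jag2, Notch1, Abcg1, Hoxa5, Hoxc6, Hoxc8, S100a4, Rpl23a, Rpl24, Nme2 and Xist are uncertain because another annotated gene overlaps them on the same strand. Reads from genes that overlap on opposite strands, such as Krt5, Cyp2f2, Aqp4, Mki67, Ccl2, Fgf7 and Fgf10, and reads shared with ribosomal protein pseudogenes or close paralogs could not be parted either. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.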

Results

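The study asked how nylon 6,6 microfibers act on lung organoids, in which primary mouse lung epithelial cells grow together with fibroblasts in Matrigel. Each well of a 6-well plate received 200000 EpCAM-positive cells from female C57BL6 mice and 200000 cells of CCL206, a lung fibroblast line from a male ddY mouse. Fibers of 12 by 31 micrometers were mixed in at 0, 12000 or 30000 per well, which the labels equate to 2000 and 5000 fibers in smaller wells. After 7 days, magnetic beads against EpCAM, a surface protein of epithelial cells, parted an epithelial from a fibroblast fraction, and RNA of both was sequenced. The libraries form 6 groups of 4, with mouse 1 to 4 in every group.

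Summed transcript counts were 21222034 to 28232472 per library in epithelial controls, 20103389 to 31119155 at 12000 fibers and 6767842 to 9234052 at 30000 fibers. In the fibroblast fraction they were 7651372 to 9022426 in controls, 10478189 to 12625242 at 12000 fibers and 10717290 to 12377774 at 30000 fibers. The epithelial libraries at 30000 fibers stood apart in more than depth. Mitochondrial genes took 15.6% ± 0.882 of their counts on representative transcripts (SD, n = 4), against 6.44% ± 1.1 in controls and 6.08% ± 0.727 at 12000 fibers. Their counts also lay more on isoforms nearer the 3′ ends of genes, by 0.489 to 0.582 on a log2 scale, while controls lay between -0.057 and 0.037 and the 12000-fiber libraries between -0.101 and -0.056. This index, called the 3′ shift or coverage shift below, rests on isoform counts and not on read positions. Isoform use or isoform length may move it too.

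The comparison of 12000 fibers with control in the epithelial fraction asked whether the lower fiber number changes expression there. Genes of airway basal, secretory, goblet and ciliated cells were far lower with fibers. Krt5, a keratin of basal cells, fell from 702 ± 197 to 52.6 ± 20.0 CPM (SD, n = 4; log2 fold change -3.75 ± 0.33, SE). Reg3g, a secreted antimicrobial lectin of the airway, fell from 289.0 ± 118 to 2.28 ± 1.39 CPM (log2 -6.89 ± 0.44), and the gel-forming mucin Muc5b fell from 61.8 ± 33.0 to 0.637 ± 0.69 CPM (log2 -6.35 ± 0.64). Foxj1, the transcription factor that drives motile cilia, fell from 60.6 ± 12.5 to 25.4 ± 3.09 CPM (log2 -1.25 ± 0.13). The sterol exporter gene Abca1 rose from 54.2 ± 11.3 to 390.9 ± 21.8 CPM (log2 2.85 ± 0.15), and fibroblast genes such as Dcn rose (log2 1.49 ± 0.21). In all, 5231 of 13759 genes changed, 2575 higher and 2656 lower (edgeR, adjusted p under 0.05). The count was 5190 without the 4 libraries of 30000 fibers in the fit.

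Among ciliated cell genes, 30 of 32 tested were lower and none higher (31 lower adjusted over the list alone), with a median log2 change of -1.36. Foxj1 (chromosome 11, 116330704 to 116335399 in mm10) was joined by Lrrc23 (log2 -4.23 ± 0.37), by Dnah5, a heavy chain of the outer dynein arm (-2.77 ± 0.29), and by Ccno, a regulator of centriole amplification (-2.69 ± 0.30). Of basal cell genes, 14 of 15 were lower and none higher, also adjusted over the list alone, with a median of -3.63. They included Krt5 (chromosome 15, 101707070 to 101712898), the hemidesmosome integrin genes Itgb4 (-1.73 ± 0.12) and Itga6 (-1.10 ± 0.07), and Dapl1 (-4.27 ± 0.44). Of club and secretory genes, 17 of 21 were lower and 1 higher (17 and 2 adjusted over the list alone). Scgb3a1 (-6.32 ± 0.67), Scgb3a2 (-5.65 ± 0.51), Bpifa1 (-5.37 ± 0.51) and the club cell cytochrome Cyp2f2 (-4.90 ± 0.33) fell. Scgb1a1, the classical club cell secretoglobin, had a log2 change of 0.79 ± 0.33 (adjusted p = 0.09), which became 0.94 (adjusted p = 0.0492) without the 12000-fiber library of mouse 3. Of goblet and mucin genes, 11 of 15 were lower and 2 higher (12 and 2 adjusted over the list alone), with Muc5ac at -2.54 ± 0.22 and Agr2, a protein folding factor of mucus cells, at -7.04 ± 0.61. At 12000 fibers Agr2 stood at 0 CPM in all libraries but that of mouse 1 (0.269 CPM), so the size of its fall is uncertain. Camera called the lists of ciliated (adjusted p = 2.06e-12), basal (2.95e-12), club (2.05e-11) and goblet genes (7.39e-06). None of these calls held with an estimated correlation (adjusted p = 0.17 for each of the 4 lists).

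The NOTCH, cholesterol synthesis and aryl hydrocarbon receptor lists fell in the same libraries, while that of fatty acid synthesis and lipid storage rose. In the NOTCH pathway, which directs the choice between secretory and ciliated fates, 9 of 12 genes were lower and none higher, also adjusted over the list alone. The receptor gene Notch1 fell by 1.16 ± 0.08, the ligand gene Jag2 by 2.32 ± 0.15 and the target gene Hey1 by 4.08 ± 0.29 on the log2 scale (camera adjusted p = 3.55e-05, adjusted p = 0.17 with an estimated correlation). Of cholesterol synthesis and SREBP2 target genes, 19 of 24 were lower and none higher (20 lower adjusted over the list alone), with Lss at -0.94 ± 0.08, Idi1 at -0.92 ± 0.10 and Hmgcs1 at -0.73 ± 0.07 (camera adjusted p = 4.24e-09, adjusted p = 0.29 with an estimated correlation). The liver X receptor targets Abcg1 (3.39 ± 0.25) and Apoe (1.98 ± 0.36), known for sterol export, and the desaturase gene Scd1 (1.83 ± 0.18) rose, as did 8 of 22 genes of fatty acid synthesis and lipid storage against 3 that fell, also adjusted over the list alone (camera adjusted p = 0.0393, adjusted p = 0.53 with an estimated correlation). With the fibroblast level as a covariate, the median of that list went from 0.21 to 0.01. In the list of aryl hydrocarbon receptor targets, which answer xenobiotics, 5 of 6 tested genes were lower and none higher, also adjusted over the list alone. The targets Cyp1a1, Cyp1a2 and Ahrr had no listed transcript and were not tested, and the receptor gene Ahr is counted among the 6. Cyp1b1 fell by 1.28 ± 0.11, Aldh3a1 by 1.63 ± 0.15 and Ahr itself by 1.30 ± 0.14 (camera adjusted p = 2.73e-04, adjusted p = 0.17 with an estimated correlation).

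Of proliferation genes, 23 of 31 were lower and 3 higher (25 and 3 adjusted over the list alone), with the cycling cell marker Mki67 at -1.23 ± 0.10, Hmgb2 at -1.33 ± 0.12 and Cenpf at -1.07 ± 0.09 (camera adjusted p = 4.24e-09, adjusted p = 0.41 with an estimated correlation). Of hypoxia and glycolysis genes, 17 of 24 were lower and 2 higher, also adjusted over the list alone, with the carbonic anhydrase gene Car9 at -3.56 ± 0.36 and the prolyl hydroxylase gene Egln3 at -3.16 ± 0.23 (camera adjusted p = 4.34e-05, adjusted p = 0.39 with an estimated correlation).

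Fibroblast genes were higher in the same epithelial libraries. Of 27 fibroblast identity genes, 25 were higher and none lower (26 higher adjusted over the list alone), with a median of 1.07, and among them Dcn and Lum (1.07 ± 0.20) encode small matrix proteoglycans. Col1a1 rose from 295 ± 109 to 530 ± 45.1 CPM (SD, n = 4; log2 0.84 ± 0.23, adjusted p = 0.0174). Of 19 Hox genes, transcription factors of body position that fibroblasts also express, 13 were higher and 1 lower, also adjusted over the list alone, among them Hoxc8 (1.39 ± 0.18), Hoxc6 (1.33 ± 0.24) and Hoxa5 (chromosome 6, 52201754 to 52204587; 1.06 ± 0.16). The study picked Hoxa5, so its rise is not independent evidence. The growth factor genes Fgf7 (1.39 ± 0.30) and Fgf10 (0.94 ± 0.27) rose as well, while Acta2, the smooth muscle actin of myofibroblasts, had a change of 0.65 ± 0.34 (adjusted p = 0.17), which passed with the mouse as a block (0.74, adjusted p = 0.0494). Camera called fibroblast identity (adjusted p = 1.51e-10) and Hox genes (adjusted p = 2.73e-04), and neither call held with an estimated correlation (adjusted p = 0.41 and 0.50). With the fibroblast level as a covariate, 951 genes passed, 171 higher and 780 lower. In that fit Hoxa5 (0.41, adjusted p = 0.405), Hoxc6 (0.37), Hoxc8 (0.53), Fgf7 (0.00), Lum (0.08), Apoe (1.25) and Epcam (-0.13) no longer passed, and Col1a1 (-0.11) and Fgf10 (-0.19) turned below 0. The covariate is the mean of the fibroblast identity list in the same libraries and itself rose with fibers. The fit therefore cannot part carried-over RNA from an effect of fibers, and values near 0 for members such as Col1a1 and Lum are partly built in. Errors widened too, with Scgb1a1 at 0.81 (edgeR adjusted p = 0.618).

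Alveolar type 2 genes, which serve surfactant, were higher in 7 of 24 and lower in 1 (camera adjusted p = 0.00637, adjusted p = 0.64 with an estimated correlation), and Sftpc, the surfactant protein C gene, had a change of 0.75 ± 0.29 (adjusted p = 0.0643), which passed under DESeq2 (adjusted p = 0.0212), with summed transcripts (0.0439) and without the 12000-fiber library of mouse 3 (0.0453). Camera also called neuroendocrine and tuft cell genes (4 of 5 higher, adjusted p = 0.00637), MHC class II (5 of 7 higher, 0.00358), p53 targets (12 of 20 higher, 3 lower, 0.0169), transitional alveolar genes (9 of 20 higher, 3 lower, 0.0358), myofibroblast and matrix genes (11 of 22 higher, 3 lower, 0.0382), YAP targets (7 of 14 higher, 2 lower, 0.0382), ribosomal proteins (16 of 71 higher, 1 lower, 0.00637) and oxidative phosphorylation (8 of 32 higher, 0.0382). It called pan-epithelial genes (11 of 25 lower, 4 higher, 0.0382) and the interferon response (10 of 25 lower, 2 higher, 0.0382) as lower. With an estimated correlation the adjusted p of these lists ran from 0.39 to 0.67. Several of these rises shrank with the fibroblast level as a covariate, in a fit that cannot part carried-over RNA from an effect of fibers. The median went from 0.56 to -0.02 for alveolar type 2 genes, from 0.81 to -0.03 for MHC class II, from 0.44 to -0.03 for myofibroblast genes, from 0.22 to 0.01 for YAP targets, from 0.29 to 0.06 for p53 targets and from 1.04 to 0.30 for neuroendocrine and tuft cell genes. It went up for transitional alveolar genes (0.17 to 0.27), ribosomal proteins (0.09 to 0.21) and oxidative phosphorylation (0.08 to 0.17). For the lists called lower it went from -0.19 to -0.04 for pan-epithelial genes and from -0.24 to -0.30 for the interferon response. Epcam itself fell by 0.43 ± 0.09, Grhl2, an epithelial transcription factor, by 0.69 ± 0.08, and the tight junction gene Cldn4 rose by 0.69 ± 0.09. The lists of alveolar type 1 cells (6 of 19 higher, 5 lower), growth factors (7 of 24 higher, 2 lower), NRF2 targets (9 of 21 higher, 8 lower), the unfolded protein response (7 of 24 higher, 8 lower), inflammation (8 of 25 higher, 10 lower), WNT targets (5 of 12 higher, 2 lower), the TGF-beta and BMP response (7 of 16 higher, 5 lower), immediate early and heat shock genes (3 of 18 higher, 5 lower), immune cells (1 of 5 higher, 1 lower) and endothelial and mesothelial cells (1 of 5 higher, 1 lower) did not pass. Adjusted over the list alone, the counts were 6 higher for MHC class II, 13 higher and none lower for ribosomal proteins, 7 higher for oxidative phosphorylation, 12 lower for pan-epithelial genes, 12 lower for the interferon response, 4 lower for YAP targets, 7 higher for alveolar type 1 cells, 10 higher for NRF2 targets, 9 lower for the unfolded protein response, 9 higher and 11 lower for inflammation, 3 lower for WNT targets and 6 lower for heat shock genes. For the other lists named here they did not differ from the counts over all genes. Median and mean had opposite signs for alveolar type 1 cells (0.07 and -0.15) and for the unfolded protein response (-0.10 and 0.08).

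**Figure D1:**
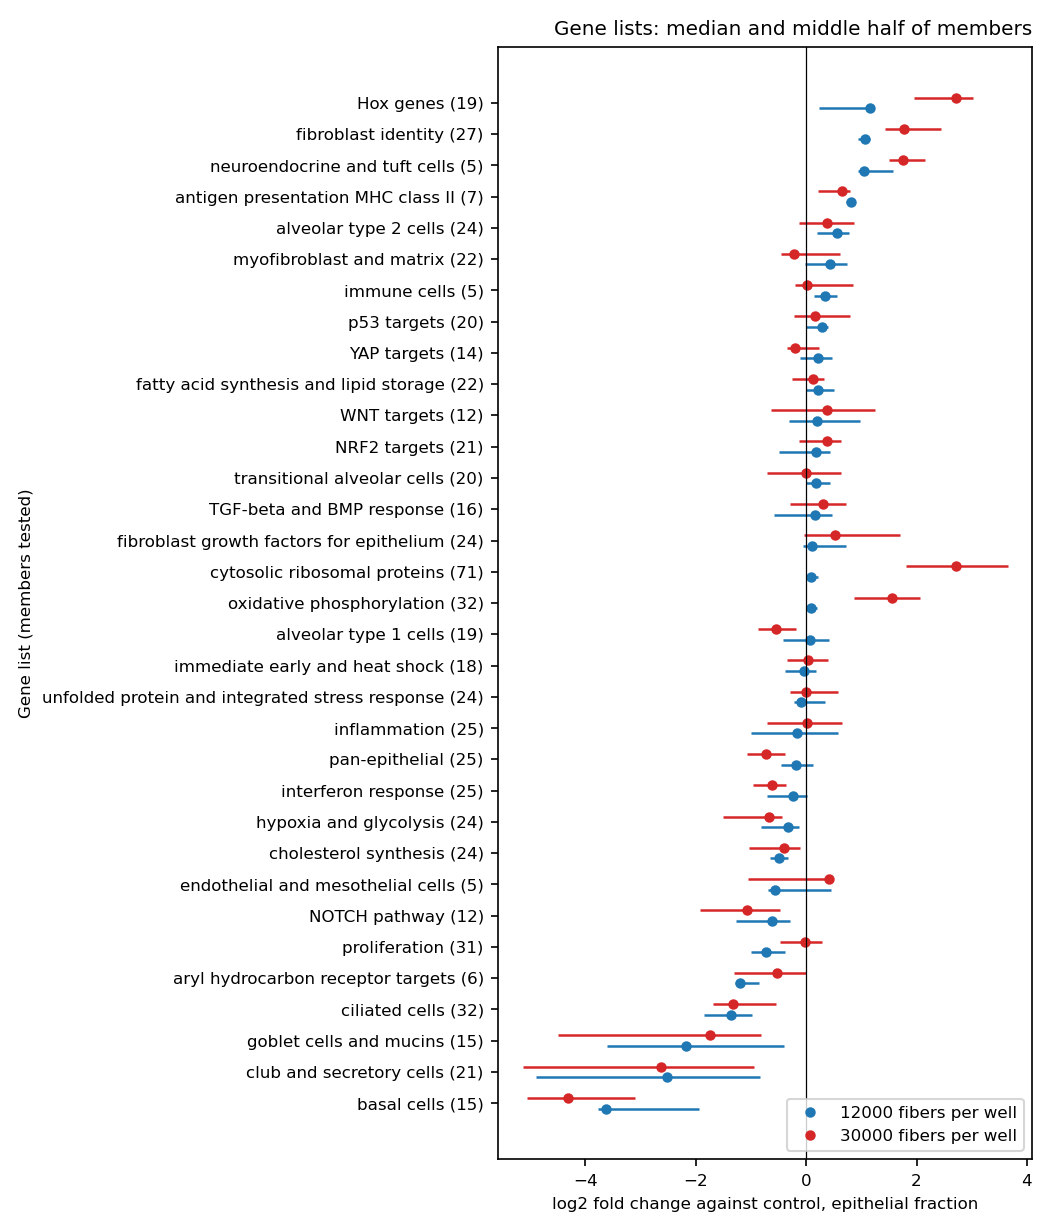
Median log2 fold change against control of each gene list in the epithelial fraction (points) with the quartile range of its members (lines) at 12000 and 30000 fibers per well, 4 libraries per group. Basal cell genes lie lowest at both doses (-3.63 and -4.32), and ribosomal protein genes move from 0.09 at 12000 fibers to 2.72 at 30000.

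The comparison of 30000 fibers with control asked the same of the higher fiber number. The airway genes were again lower, and genes of ribosomal proteins, the respiratory chain, Hox factors and fibroblasts were higher. Krt5 fell to 18.3 ± 7.59 CPM (SD, n = 4; log2 -5.25 ± 0.40, SE), Foxj1 to 14.6 ± 2.76 CPM (-2.06 ± 0.17) and Muc5ac to 1.67 ± 0.506 CPM (-2.76 ± 0.30). Rpl36, a protein of the large ribosomal subunit (chromosome 17, 56613416 to 56614243), rose from 22.5 ± 1.96 to 674 ± 63.6 CPM (4.91 ± 0.10), and the chemokine gene Ccl2 from 6.42 ± 2.43 to 175 ± 29.9 CPM (4.78 ± 0.19). Of 13759 genes, 9026 changed, 4434 higher and 4592 lower (edgeR, adjusted p under 0.05). This comparison cannot be made without the libraries of higher mitochondrial share and 3′ shift, since all 4 of its fiber libraries share both.

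The ribosomal and respiratory groups moved together with that 3′ shift and mitochondrial share. Of 71 ribosomal protein genes, 67 were higher and 3 lower, also adjusted over the list alone, with a median of 2.72. Rpl23a (4.67 ± 0.09) and Rpl24 (4.34 ± 0.07) stood beside Rpl36, and all 3 can share reads with pseudogenes. Ribosomal protein genes took 0.88% of the counts on representative transcripts in controls, 0.95% at 12000 fibers and 4.3% at 30000. These values and the 3′ shift are relative, so they do not tell which libraries lie nearer the true shares of short transcripts. Of 32 oxidative phosphorylation genes, 29 were higher and 2 lower, also adjusted over the list alone, with Cox6c, a subunit of complex IV, at 3.46 ± 0.08 and Ndufa1, a subunit of complex I, at 3.43 ± 0.11. The mitochondrial gene mt-Nd3 rose by 5.04 ± 0.25. Camera called both lists (adjusted p = 2.60e-30 and 2.26e-12), and neither call held with an estimated correlation (adjusted p = 0.32 and 0.15). Across 12905 genes the change at 30000 fibers fell with transcript length (Pearson r = -0.26 across genes, which are not independent replicates). The shortest of 5 equal classes by length had a median change of 0.50 and the longest of -0.23, against 0.04 and -0.02 at 12000 fibers. With that trend removed, the medians of ribosomal proteins and oxidative phosphorylation were 1.88 and 0.71.

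**Figure D2:**
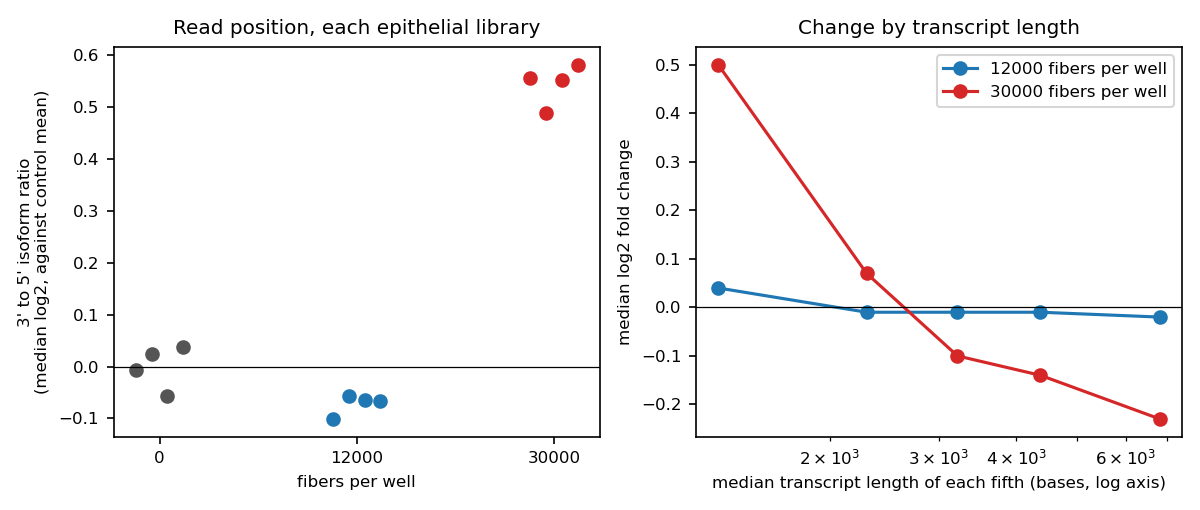
Left, log2 ratio of 3′ to 5′ isoforms (median over 3869 genes, against the control mean) in each epithelial library. Right, median log2 fold change against control of 5 equal classes of transcript length (bases, log axis), which falls from 0.50 to -0.23 at 30000 fibers and stays between 0.04 and -0.02 at 12000.

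Airway groups were again mostly lower at 30000 fibers. Basal cell genes were lower in 13 of 15 and higher in 1 (camera adjusted p = 9.95e-06), with Itgb4 at -2.95 ± 0.13 and Itga6 at -1.75 ± 0.08. Club and secretory genes were lower in 17 of 21 and higher in 2 (1.59e-04), with Reg3g at -7.63 ± 0.57 and Scgb3a1 at -7.04 ± 0.94, while Scgb1a1 rose from 11.5 ± 5.10 to 210 ± 25 CPM (4.15 ± 0.30). Goblet and mucin genes were lower in 12 of 15 and higher in 2 (0.0024), with Muc5b at -6.47 ± 0.85. Ciliated genes were lower in 21 of 32 and higher in 1 (7.01e-04), with Lrrc23 at -3.14 ± 0.42, and the NOTCH pathway was lower in 10 of 12 and higher in 1 (0.00152), with Jag2 at -3.91 ± 0.21. The counts of these 5 lists adjusted over the list alone did not differ from those over all genes. With an estimated correlation their adjusted p ran from 0.46 to 0.48. With the fibroblast covariate the medians went from -4.32 to -3.13 for basal, from -2.63 to -2.07 for club, from -1.74 to -1.12 for goblet, from -1.33 to -0.69 for ciliated and from -1.07 to -0.94 for NOTCH genes. The surface keratin gene Krt4 (-7.27 ± 0.57), the water channel gene Aqp4 (-6.34 ± 0.41) and the laminin gene Lama1 (-6.10 ± 0.45) were among the largest falls.

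Pan-epithelial genes were lower in 19 of 25 and higher in 1 (21 lower adjusted over the list alone; camera adjusted p = 3.05e-05), with Epcam at -1.44 ± 0.09 and Grhl2 at -1.78 ± 0.10. Alveolar type 1 genes were lower in 11 of 19 and higher in 2 (0.0346), with Krt7 at -2.01 ± 0.08. Cholesterol synthesis was lower in 15 of 24 and higher in 2 (0.00457), with Hmgcs1 at -1.01 ± 0.07. Hypoxia and glycolysis genes were lower in 20 of 24 and higher in 2 (8.44e-05), and the interferon response was lower in 15 of 25 (14 adjusted over the list alone; 0.00867). Where no other count is given, adjustment over the list alone gave the same counts. With an estimated correlation the adjusted p of these 5 lists ran from 0.46 to 0.63. Aryl hydrocarbon receptor targets were lower in 3 of 6 (camera adjusted p = 0.234), with Cyp1b1 at -1.72 ± 0.13 and Ahr at -1.46 ± 0.15. Proliferation genes went both ways, 8 of 31 higher and 10 lower (camera adjusted p = 0.937), with Mki67 at -0.89 ± 0.10 and the replication clamp gene Pcna at 2.00 ± 0.09. In the inflammation list 7 of 25 were higher and 8 lower (camera adjusted p = 0.909), and besides Ccl2 the chemokine gene Ccl7 rose by 3.69 ± 0.17. The metallothionein gene Mt1, which answers metals and stress, rose from 122 ± 15.5 to 651 ± 44.0 CPM (2.41 ± 0.09), after 0.63 ± 0.08 at 12000 fibers. Sftpc changed by 1.11 ± 0.29 (adjusted p = 0.00675), but by 0.18 (adjusted p = 0.61) with the length and GC trend removed, and Sftpa1 by 2.84 ± 0.42.

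Fibroblast identity genes were higher in 25 of 27 and lower in 1 (26 and 1 adjusted over the list alone; camera adjusted p = 1.35e-07), with S100a4 at 4.83 ± 0.23, Dcn at 3.30 ± 0.21 and Col1a1 at 1.59 ± 0.24. Hox genes were higher in 18 of 19, also adjusted over the list alone (1.02e-07). Hoxa5 rose from 5.21 ± 1.60 to 56.0 ± 2.96 CPM (3.44 ± 0.15), Hoxc6 by 3.30 ± 0.23 and Hoxc8 by 3.01 ± 0.18, and Fgf7 (2.85 ± 0.30), Fgf10 (1.78 ± 0.29) and Acta2 (2.04 ± 0.35) rose too. All 5 neuroendocrine and tuft cell genes tested were higher (camera adjusted p = 0.025). With an estimated correlation the adjusted p of the 3 lists was 0.52, 0.46 and 0.46. With the fibroblast covariate the median went from 1.76 to 0.15 for neuroendocrine and tuft cell genes and from 2.72 to 0.90 for Hox genes. The remaining lists did not pass camera (lowest adjusted p = 0.121, growth factors). Median and mean had opposite signs for myofibroblast genes (-0.22 and 0.08) and endothelial and mesothelial genes (0.41 and -0.21). With the fibroblast level as a covariate 3169 genes passed, 1382 higher and 1787 lower. Fgf7 (0.19), Lum (0.16), Hoxc6 (1.49), Mki67 (-0.36), Ahr (-0.71), Aldh3a1 (-0.06), Cenpf (-0.63) and Scd1 (0.39) no longer passed in that fit, Sftpa1 missed the threshold at a log2 change near that without the covariate (2.43, adjusted p = 0.268), and Col1a1 (-0.24), Acta2 (-0.10), Fgf10 (-0.39) and Sftpc (-0.29) turned below 0.

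Xist, which only the female epithelial cells should express, changed by 0.06 ± 0.10 at 12000 fibers (adjusted p = 0.66) and by 0.07 ± 0.10 at 30000 (adjusted p = 0.546), where it passed only with the length and GC trend removed (0.19, adjusted p = 0.0412). The Y-linked gene Kdm5d, which the male fibroblast line could carry, lay at 2.07 ± 0.814 CPM in controls and 2.43 ± 0.462 CPM at 12000 fibers (log2 0.20 ± 0.29, adjusted p = 0.62). At 30000 fibers it fell to 0.402 ± 0.30 CPM (SD, n = 4; -2.25 ± 0.57), near the level of a single count, a call that ended with the fibroblast covariate (-0.61, adjusted p = 0.70). The Y-linked genes Ddx3y, Eif2s3y and Uty had no listed transcript in the epithelial counts.

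**Figure D3:**
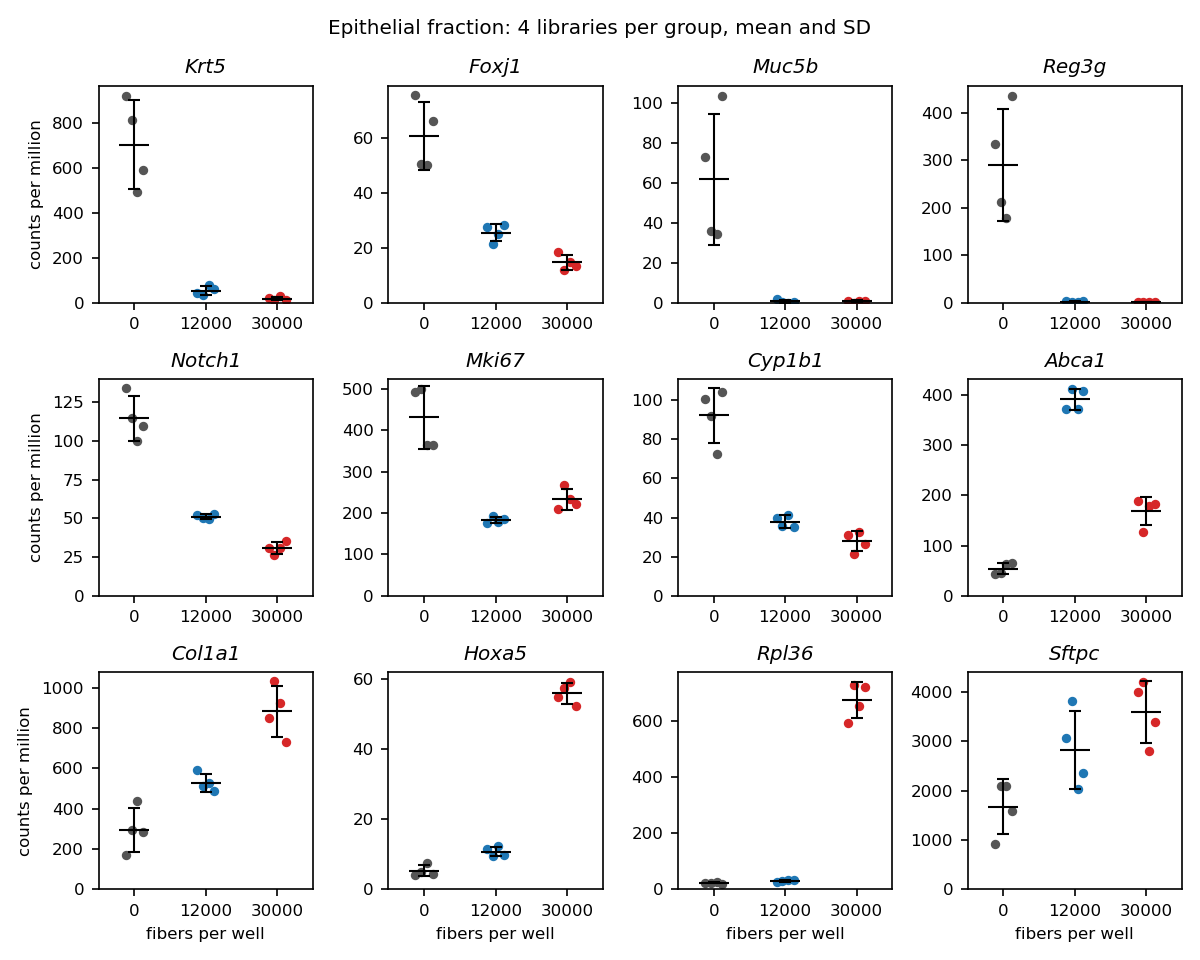
CPM of 12 genes in each epithelial library by fibers per well, with the mean and SD of 4 libraries. Krt5 falls from 702 to 52.6 and 18.3 CPM, Abca1 goes from 54.2 to 390.9 and 169 CPM, and Hoxa5 and Rpl36 stand apart at 30000 fibers (56.0 and 674 CPM).

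The comparison of 30000 with 12000 fibers asked what the higher fiber number changes beyond the lower. Proliferation, fibroblast, Hox, ribosomal and respiratory genes were higher at 30000 than at 12000 fibers, and general epithelial genes were lower. All 4 libraries at 30000 fibers share the 3′ shift and the higher mitochondrial share, so these cannot be parted from fiber number for any list. Against control, the median of proliferation genes was -0.73 at 12000 fibers and -0.02 at 30000, so that list rose from a fall and not above control. Epcam fell by a further 1.02 ± 0.09 (SE, n = 4 per group), Grhl2 by 1.08 ± 0.10, Cldn4 by 1.39 ± 0.09 and Krt7 by 1.51 ± 0.08 on the log2 scale. Ccnb1 (2.17 ± 0.20), Cdk1 (1.09 ± 0.11) and Pcna (2.17 ± 0.09), genes of the cell cycle and DNA replication, rose, and Mki67 rose by 0.35 ± 0.11. The call for Cdk1 ended with summed transcripts (0.22, adjusted p = 0.127). In all 7621 of 13759 genes changed, 3893 higher and 3728 lower (edgeR, adjusted p under 0.05).

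Proliferation genes were higher in 22 of 31 and lower in none (23 higher adjusted over the list alone; camera adjusted p = 6.48e-05). Pan-epithelial genes were lower in 18 of 25 and higher in none (19 and 1 adjusted over the list alone; 6.48e-05). Fibroblast identity was higher in 17 of 27 and lower in 1 (0.00289), and Hox genes were higher in 18 of 19 (3.67e-07), with Hoxa5 at 2.38 ± 0.14. Basal cell genes were lower in 7 of 15 and higher in 1 (0.0488): Krt5 fell by 1.5 ± 0.42 (-0.98, adjusted p = 0.173, with the fibroblast covariate) while Snai2, a transcription factor that fibroblasts also express, rose by 2.36 ± 0.15. Alveolar type 1 genes were lower in 9 of 19 and higher in 2 (0.0375), and hypoxia and glycolysis genes were lower in 12 of 24 and higher in 3 (0.0375). Adjusted over the list alone, the counts of these 5 lists did not differ from those over all genes. With an estimated correlation the adjusted p of each of the 7 lists was 0.86. With the fibroblast covariate the medians shrank for basal (-1.18 to -0.48), Hox (1.77 to 0.93), pan-epithelial (-0.53 to -0.47) and, as the covariate dictates, fibroblast identity genes (0.80 to -0.13). They grew for proliferation (0.525 to 0.717), alveolar type 1 (-0.43 to -0.64) and hypoxia and glycolysis genes (-0.34 to -0.41). Ribosomal proteins (67 of 71 higher, 3 lower, camera adjusted p = 2.36e-36) and oxidative phosphorylation (28 of 32 higher, 2 lower, 8.99e-14) were again called, also with the same counts adjusted over the list alone (adjusted p = 0.21 and 0.11 with an estimated correlation). They rose in the libraries with the 3′ shift and the higher mitochondrial share, and their medians went from 2.63 to 1.80 and from 1.51 to 0.58 with the length and GC trend removed.

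The ciliated (8 of 32 higher, 2 lower), club (5 of 21 higher, 1 lower) and goblet lists (2 of 15 higher, 1 lower) did not pass camera between the doses (adjusted p = 0.499, 0.76 and 0.808), with the same counts adjusted over the list alone. Median and mean had opposite signs for NRF2 targets (-0.04 and 0.30) and alveolar type 2 genes (-0.07 and 0.10). Foxj1 fell by a further 0.81 ± 0.18, a call that ended with the trend removed (-0.44, adjusted p = 0.0884) and with the fibroblast covariate (-0.47, adjusted p = 0.0513), while Tmem212 (2.20 ± 0.34) and Dynlrb2 (2.77 ± 0.43), other genes of ciliated cells, rose. Scgb1a1 rose by 3.36 ± 0.29 and Ccl2 by 3.42 ± 0.17. Muc5ac (-0.22 ± 0.39, adjusted p = 0.65) and Sftpc (0.35 ± 0.29, adjusted p = 0.32) did not pass, though Sftpc did with summed transcripts (1.02, adjusted p = 0.00569). Cyp1b1 fell by a further 0.44 ± 0.14 (adjusted p = 0.0129), a call that ended with summed transcripts, where the sign reversed (0.11, adjusted p = 0.52), with the fibroblast covariate (-0.20, adjusted p = 0.356), and narrowly with thinning (-0.37, adjusted p = 0.0659) and without the 30000-fiber library of mouse 2 (-0.33, adjusted p = 0.0543). The rise of Col1a1 (0.74 ± 0.23) stayed near that size but missed the threshold without the 12000-fiber library of mouse 4 (0.70, adjusted p = 0.0538) or the 30000-fiber library of mouse 2 (0.66, adjusted p = 0.0617). That of Fgf10 (0.84 ± 0.27) missed it without the 30000-fiber library of mouse 3 (0.74, adjusted p = 0.0514) or with thinning (0.60, adjusted p = 0.108).

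The responses to both fiber numbers were compared over the 13759 epithelial genes. Of the genes higher at 12000 fibers, 1702 were also higher at 30000, against 830 if the lists were independent, and 1978 were lower at both, against 886. Changes in opposite directions were called for 360 genes, against 1715. The log2 changes had a Pearson r of 0.696 and a Spearman rho of 0.587 across genes, which are not independent replicates. Both comparisons share the control libraries, and simulated unchanged groups sharing them gave r = 0.406. With 2 separate controls for each dose r was 0.599 and 0.69. The covariance was 0.5395 against 0.0139 in the simulation.

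In the fibroblast fraction the entries carry no usable identity, so the comparison can say how many changed and not which genes. At 12000 fibers 30075 of 55343 entries changed, 14882 higher and 15193 lower, and at 30000 fibers 30585 changed, 15291 higher and 15294 lower (edgeR, adjusted p under 0.05). Entries stand for transcripts that can share reads, so these are not numbers of genes. Upper quartile normalization moved the median of all entries to 0.15 and 0.16 on the log2 scale and the calls to 18743 higher and 12040 lower at 12000 fibers and 19072 higher and 12325 lower at 30000.

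Between 30000 and 12000 fibers, 299 fibroblast entries changed, 67 higher and 232 lower. With the mouse as a block 778 changed, 185 higher and 593 lower. Leaving out a library gave 78 to 260, and all 8 libraries but the 12000-fiber library of mouse 2 moved the count by more than 1.5 times. The log2 changes at 12000 and 30000 fibers had a Pearson r of 0.957 and a Spearman rho of 0.952 across entries. Simulated unchanged groups sharing the controls gave r = 0.571, and 2 separate controls for each dose gave 0.847 and 0.83. The covariance was 0.6925 against 0.0278 in the simulation. Higher at both doses were 12911 entries (4112 if independent) and lower at both 13541 (4199), while 8 changed in opposite directions (8310 if independent).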

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

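The tests of a read coverage shift and of a graded response of ribosomal protein genes, of Hoxa5 within the fibroblast list, of Xist and of separate handling of control cultures were chosen after their results had been seen. The test of fibroblast genes within dose groups was added after the rise of these genes had been seen. Libraries were compared with the other 3 of their group, and chance alone sets 1 in 20 groups apart. Of 339 groups, 15 held a library set apart, against 16.9 expected.

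The 12000-fiber library of mouse 1 had 31119155 counts, against 20103389 to 21000316 in the others, and a mean log2 level of goblet genes of 2.85 against 2.43 to 2.49. It also had 23.0 CPM of Cyp2f2 against 16.5 to 17.2, and 0.269 CPM of Agr2 against 0. In the 30000-fiber library of mouse 1, Cyp2f2 was at 43.9 CPM against 19.7 to 20.8, Agr2 at 0.392 CPM against 0, and Dapl1 at 0 against 0.294 to 0.353. In that of mouse 2, Ahr was at 57.5 CPM against 78.8 to 81.5, Abca1 at 127 CPM against 179 to 188, S100a4 at 456.5 CPM against 293 to 307, and Ccl7 at 60.7 CPM against 41.4 to 42.3. That of mouse 3 had a mitochondrial share of 14.3% against 16.0% to 16.3% and 0.883 CPM of Krt4 against 0.334 to 0.392. Among controls, mouse 3 had a mean log2 level of pan-epithelial genes of 7.06 against 7.18 to 7.20, and mouse 1 had 506 CPM of Itga6 against 412 to 419.

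Ribosomal protein genes were higher at 30000 fibers by a median of 2.72, in libraries whose counts had moved towards isoforms nearer the 3′ ends. The median lay above 100% of 1000 lists matched on length, GC content and level (central range 0.50 to 1.1, highest 1.44). It stayed at 1.88 with the trend removed. A coverage shift of the size seen in those matched genes is therefore argued against. The match was imperfect, with a median length of 887 bases in the list and 1469 in the matched genes. A larger shift in the shortest transcripts was not tested, so how much of the rise comes from coverage stays open. Thinning to the lowest total kept 0.99 of the median change. Thinning leaves the expected share of each gene as it was, so this outcome was nearly fixed. It does not test what lowered the totals at 30000 fibers. A graded response to fiber number stays open, because the median at 12000 fibers was 0.10 (SE 0.09 over 4 mice), barely above its error, and biology and RNA quality are confounded at 30000 fibers.

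Fibroblast identity genes rose in the epithelial fraction by medians of 1.07 and 1.78, and Hoxa5 by 1.06 and 3.44; a coverage shift is argued against, because the list's median with the trend removed was 1.13 of its value. Fibroblast RNA carried through the EpCAM selection may contribute. Within dose groups the list's first component took 0.827 of the variance, above 100% of 1000 lists of similar level (highest 0.453). Those lists were random genes, so any genes regulated together could exceed them, and the component does not tell carry-over from a shared program. Hoxa5 exceeded 96.3% of the members at 30000 fibers (48.1% at 12000), inside their central range of 0.34 to 3.85, yet its call there held with the fibroblast covariate (2.21, adjusted p = 2.83e-04), as did those of the members Dcn (1.52) and S100a4 (2.94) but not of Lum (0.16), around a list median of -0.19 that the covariate sets near 0. Values that go the other way are Kdm5d of the male line, at 0.20 and -2.25 on few counts, and the myofibroblast and matrix list at 30000 fibers, with a median of -0.22 (7 higher, 8 lower). The Y-linked genes Ddx3y, Eif2s3y and Uty had no listed transcript. Whether the line expresses them is unknown, since the fibroblast entries carry no names. The component over all 12 libraries (0.90) decides nothing, since any shared rise gives it. Xist (0.06 at 12000 fibers) did not fall in the main fit at either dose, but a loss smaller than its standard error, given above, cannot be seen. A true rise in epithelial cells stays open and untested.

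Fibroblast controls stood apart from both fiber doses, with 30075 and 30585 entries changed but 299 between the doses. Depth is argued against, because thinning kept at least 0.896 of the entries changed, and so is a single deviant control, because leaving out any control kept at least 0.936 of those at 30000 fibers. Handling or sequencing of the controls apart from the fiber cultures cannot be told apart from the fibers, since it would coincide with the treatment. Same-mouse correlations of controls with fiber libraries (-0.076 to 0.141, 1 of 8 below 0) do not decide it. An effect of fibers that is already complete at 12000 per well may give the same picture and was not tested.

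In 5 of the comparisons the real grouping was 1 of 35 splits of its 8 libraries with as many calls, the smallest share these libraries allow if unpaired. A random parting is argued against only on that reading. The mouse numbers pair the libraries, and only 8 splits part all pairs, so the share is 1 of 8, too large to exclude it. Every other split also mixes the groups compared, so a real difference widens its spread and lowers its count. The highest count of the other splits was 0 against real values of 5231, 9026 and 7621 in the epithelial fraction and 30075 and 30585 in the fibroblast fraction. At an unadjusted p under 0.05, edgeR called at most 2534, 2574, 1869, 11605 and 11408 in those other splits, against real values of 6372, 9448, 8247, 32773 and 33083. For 30000 against 12000 fibers in the fibroblast fraction the evidence is weaker. There 1 of 35 splits had as many adjusted calls (299, at most 214 in the others), but 4 of 35 had as many unadjusted calls (4740, at most 6730). Among the 8 splits that part all pairs of mice the others had 0 adjusted and at most 2347 unadjusted calls by edgeR, but here too 1 of 8 is too large a share to exclude a random parting, which is left open for that count.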

How the results depend on the processing

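Summed transcripts, each transcript tested, the length and GC trend and thinning were chosen only after the data had been seen, and the other alternatives before. A minimum absolute log2 fold change of 1 left 1241, 3306 and 1977 epithelial genes (12000 fibers, 30000 fibers, and 30000 against 12000) and 9153, 9550 and 45 fibroblast entries. The fibroblast covariate left 951 and 3169 epithelial genes against control, and testing each transcript gave 19932, 42863 and 39096 transcripts. For 30000 against 12000 fibers in the fibroblast fraction the count of 299 became 778 with the mouse as a block, 822 with no filter, 562 with only the 2 groups and 195 with thinning. Without the 12000-fiber library of mouse 1, 3 or 4 it was 154, 188 or 137, and without the 30000-fiber library of mouse 1, 2, 3 or 4 it was 78, 91, 168 or 162. Leaving out a library gave 4441 to 5414, 8605 to 9008 and 7067 to 7267 genes in the epithelial comparisons and 27997 to 30134, 28149 to 30750 and 78 to 260 entries in the fibroblast ones. Camera passed 23, 15 and 9 lists, but 0, 0 and 0 with an estimated correlation (lowest adjusted p 0.17, 0.15 and 0.11; 6, 2 and 2 lists at an unadjusted p under 0.05), while fry passed 21, 24 and 18. The block gave 23, 15 and 9 lists again and reversed only the direction of p53 targets between the doses (adjusted p = 0.937). With it 5521, 9141 and 7769 epithelial genes and 31035 and 31494 fibroblast entries against control passed. Among named genes it ended the call of H2-Aa at 12000 fibers (0.88, adjusted p = 0.0764) and let Acta2 pass there, and among named genes and lists it changed no other call. The r of both doses was 0.696 in epithelial genes, against 0.694 with the block and 0.599 and 0.69 with split controls, and 0.957 in fibroblast entries, against 0.847 and 0.83 with split controls. Signs of named genes reversed with the fibroblast covariate at 12000 fibers for Acta2 (-0.46), Ciita (-0.02), Col1a1 (-0.11), Fgf10 (-0.19), H2-Aa (-0.03) and Hgf (-0.09). At 30000 fibers they did for Acta2 (-0.10), Cd14 (0.08), Cd74 (-0.59), Col1a1 (-0.24), Fgf10 (-0.39), H2-Aa (-0.70), H2-DMa (-1.0), Hgf (-0.38), Lef1 (-0.08), Sftpc (-0.29), Uchl1 (-0.30) and Xist (-0.04), and between the doses for Col1a1 (-0.13), Fgf10 (-0.19), Lef1 (-0.06), Muc5ac (0.02), Sftpc (-0.32) and Xist (-0.04). Xist, near 0 throughout, also reversed at 12000 fibers without the control of mouse 2 (-0.01) or the 12000-fiber library of mouse 4 (-0.02), with up to 0.13 without that of mouse 1. Between the doses it reversed with upper quartile normalization (-0.02), without the 12000-fiber library of mouse 1 (-0.06) or 3 (-0.01), and without the 30000-fiber library of mouse 2 (-0.05) or 4 (-0.01), with up to 0.09 without the 12000-fiber library of mouse 4. Also between the doses, summed transcripts reversed Cyp1b1 (0.11) and Muc5ac (0.00), and trend removal reversed Gsta4 (-0.12), Muc5ac (0.07) and Sftpc (-0.49). Of 455 results for named genes, DESeq2 left 452 and the covariate 318 with the same call. The list medians under the covariate at 12000 and 30000 fibers were -2.78 and -3.13 for basal cells, -2.05 and -2.07 for club cells, -0.95 and -0.69 for ciliated cells, -0.05 and 0.90 for Hox genes, 0.21 and 3.06 for ribosomal proteins, -0.05 and -0.19 for fibroblast identity, -0.03 and -1.0 for MHC class II, 0.30 and 0.15 for neuroendocrine and tuft cells and -0.02 and -0.39 for alveolar type 2 cells. The comparisons at 30000 fibers cannot be made without their 4 libraries of shifted coverage, and the planned comparisons of the fractions could not be run.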

Other observations

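The genes here were named by the rule fixed before the data were examined, and no test was added for them. Not all genes of a group went with it. Snai2, in the basal list but also a gene of mesenchymal cells, fell by 1.40 ± 0.14 at 12000 fibers (SE, n = 4 per group; 13.3 ± 2.16 to 5.01 ± 0.248 CPM, SD) and stood at 25.8 ± 1.98 CPM at 30000. Among ciliated genes, Tmem212 went from 2.11 ± 0.512 CPM in controls to 0.921 ± 0.269 and then 4.38 ± 1.43 CPM, and Dynlrb2 from 2.40 ± 0.913 to 0.573 ± 0.12 and 4.09 ± 1.90 CPM. Some genes stood higher at 12000 than at 30000 fibers: Abca1 stood at 390.9 ± 21.8 and 169 ± 28.4 CPM respectively, Abcg1 at 32.4 ± 5.54 and 17.1 ± 6.81 CPM and Apoe at 316 ± 22.2 and 144 ± 49.3 CPM. Scd1, by CPM far above the others named here, went from 3871 ± 999 to 13730 ± 1940 and 10250 ± 1380 CPM.

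Among the largest rises at 30000 fibers were short genes outside the lists. Nme2, a nucleoside diphosphate kinase gene, rose by 5.13 ± 0.13 from 14.9 ± 2.23 to 520 ± 85.8 CPM. Sec61g, a subunit of the protein translocation channel, rose by 4.60 ± 0.22 from 1.13 ± 0.411 to 27.2 ± 3.49 CPM. At 12000 fibers they stood at 21.6 ± 2.52 and 1.01 ± 0.277 CPM. Lama1, a laminin chain of basement membranes, went the other way, from 71.2 ± 21.5 to 5.37 ± 2.11 and 1.02 ± 0.241 CPM.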
